A study of Mus musculus with 6 samples.

How the data were processed

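The series profiled RNA from the livers of wild-type C57Bl6 mouse embryos at embryonic day 12.5 on 6 Affymetrix Mouse Genome 430 2.0 arrays, with 1 array per group. The groups were liver cells, cells sorted for ALCAM (ALCAM+), and 4 fractions of ALCAM+ cells: PDPN+, PDPN-, ITGA8+ and ITGA8-. ALCAM is a cell adhesion molecule of the immunoglobulin family, PDPN (podoplanin) a surface glycoprotein of mesothelium and lymphatic endothelium, and ITGA8 the integrin alpha 8 subunit. Per the labels' protocols, 20 ng of total RNA per sample was amplified and labelled with biotin. Each group came from its sample's source label. There are no replicates, so no test, p-value or spread between samples was computed, and each difference is a difference between 2 arrays.

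The deposited values are intensity values on a linear scale, in whole numbers. Per the submitters' processing notes, RMA and Partek were used; their versions are not given in the sources used here. The design written before the data were examined took the values for RMA values on a log2 scale, and planned a log2 transformation if they were linear, which was done. The values were also not quantile normalised across the 6 arrays, and they fall into 2 sets. The 4 fraction arrays share a mean after trimming 2% at each end of 996 to 997 (996.44 in PDPN+, 996.78 in ITGA8-), reach down to 0, and carry no control probe set values. The liver and ALCAM+ arrays have trimmed means of 194.79 and 329.05, a minimum of 3, and values for 64 control probe sets. Levels set across the 2 sets therefore carry a difference in scale, and the differences of the 4 comparisons were taken within a set. The share of genes with ALCAM+ between its fractions, the tests of ALCAM+ against PDPN+ and the alternatives that exchange arrays between the sets cross them. So do the floor, the choice of a gene's probe set and the quantile normalisation, which use all 6 arrays.

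Of 45101 probe sets, 64 were controls, 5746 named no gene and 1280 named several genes; these were left out of the gene comparisons. The remaining 38011 named 1 gene each, for 20678 genes, of which 9607 had several probe sets. Gene symbols were taken through the Entrez identifiers from a RefSeq gene table of assembly GRCm38.p6, which matched 92.11% of these probe sets; the others kept the file's symbol. In the file 60 probe sets carried symbols that looked like dates or numbers made by a spreadsheet. Those that named 1 gene with a matched identifier took the symbol of the gene table. No genome build is given in the sources used here, so no coordinates are printed. Close paralogs, such as the globin genes, Stfa2l1 and Stfa3, or Serpina1a and Serpina1b, can share probes, and values of such genes are uncertain.

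Values were transformed to log2(intensity + 16), since some intensities are 0; the pseudocount was chosen after seeing the data. Folds are on this scale and understate the difference of low genes. Where the lower array is below the floor, the size of a fold and its rank depend on the pseudocount; this holds for 15 of the 16 genes named by size in ALCAM+ minus liver, 16 of 16 in PDPN+ minus PDPN-, 8 of 16 in ITGA8+ minus ITGA8- and 14 of 16 in ITGA8+ minus PDPN+. A gene was represented by its probe set with the highest mean over the 6 arrays. A gene entered a comparison where the higher of its 2 arrays exceeded the median of all probe set values, an intensity of 109.0. Genes were counted at 2-fold, with 4-fold as an alternative. The only error measure within these arrays is the agreement of a gene's other probe sets above the floor.

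In ALCAM+ minus liver the median over all genes was 0.90 on the log2 scale, a 1.86-fold shift, and differences are given relative to that shift. The other 3 comparisons had medians of 0.04, 0.00 and 0.04, and their differences are as deposited. Their arrays limit precision by their number.

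Gene lists were fixed before the data were examined: mesothelial, hepatic stellate cell, septum transversum and coelomic transcription factors, smooth muscle, portal fibroblast, collagen and matrix, basement membrane, integrin, epithelial junction, retinoid handling, secreted growth factor, hepatoblast, erythroid, haematopoietic progenitor, macrophage, megakaryocyte, endothelial, cardiac muscle, skeletal muscle, neural, gut and lung epithelium, proliferation, dissociation stress, housekeeping and sex-linked genes. The 25 lists hold 432 entries, of which 427 were measured; 16 measured genes are in more than 1 list, so the lists are not independent; Crb2, Itga11, Trf, Hbb-b1 and Gapdh were not among the genes measured by a probe set of their own. A list is described by its members above the floor and by the percentile of its median among 10000 random lists of the same size, matched on mean signal in 10 bins. A list is said to stand apart below the 2.5 or above the 97.5 percentile. The percentile describes these arrays and is not a p-value. A neutrophil and eosinophil list was added after the data were seen.

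Named genes follow a rule fixed before the data were examined. It takes the 3 sort marker genes in all arrays, and the 8 genes with the largest difference in each direction whose other probe sets above the floor go the same way, leaving out clone names. Many named genes had only 1 probe set above the floor and so met this rule by themselves. Others had probe sets close in size, such as Col6a2 at 5.01 and 5.17 in ALCAM+ minus liver as deposited, or far apart. In the same comparison Npnt ranged from 1.42 to 5.28, and Dcx was at -3.16 and -0.54 in the PDPN split. Igfbp7 was at 2.64 and 0.80 in the ITGA8 split. From each list it takes the 2 to 4 members with the largest difference in its direction, and a counter-example where one is needed. Some single genes that this rule takes are not reported here.

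The code was tested on simulated arrays with 200 planted genes per comparison and an assumed noise SD of 0.3 log2, the same at all signal levels. Genes were planted only where the mean signal was more than 4-fold above the floor, so recovery near the floor was not tested. For PDPN+ minus PDPN-, simulated over 12709 genes above the floor, 98.5% of the genes planted at 4-fold and 100.0% at 8-fold were counted at 2-fold, against 34.3% of those planted at 2-fold, the threshold itself. Of the unchanged genes 1.93% were counted, a share that follows from the assumed noise and is not an error rate of these arrays.

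Alternatives were the mean of a gene's probe sets, only probe sets with no suffix for shared targets, no floor, a floor at the 75th percentile, re-centring, loess (limma normalizeCyclicLoess), quantile normalisation, 4-fold, and other arrays standing for ALCAM+ or for a negative fraction. Pseudocounts of 1 and 100, agreement of another probe set, re-centred substitutes, counts without the genes of the blood lists and a hepatoblast median without abundant genes were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.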

Results

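Gene expression was measured in 6 samples of E12.5 mouse liver, 1 array each: liver cells, ALCAM+ cells, and the PDPN+, PDPN-, ITGA8+ and ITGA8- fractions of ALCAM+ cells. The series concerns the isolation of a hepatic stellate cell population that expresses integrin alpha 8; stellate cells are the vitamin A storing mesenchymal cells of the liver. Median probe set intensity was 42 in liver, 66 in ALCAM+, 181 in PDPN+, 123 in PDPN-, 173 in ITGA8+ and 200 in ITGA8-. The genes above the floor numbered 8426, 10733, 13001, 11866, 13358 and 13302 in the same order. The ITGA8+ and ITGA8- arrays had a Spearman correlation over probe sets of 0.963, and the PDPN+ and PDPN- arrays 0.913. The PDPN- array had 0.887 with ALCAM+, 0.892 with ITGA8+ and 0.909 with ITGA8-. For PDPN+ these values were 0.923, 0.917 and 0.942. With 1 array per group, a deviating PDPN- array cannot be told apart from a difference that goes with podoplanin.

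The sort markers followed the labels. Alcam intensity was 13425 in ALCAM+ and 3207 in liver. Pdpn was at 7746 in PDPN+ and 117 in PDPN-. Itga8 was at 4354 in ITGA8+ and 871 in ITGA8-, 4.93-fold higher. The fractions were not exclusive at the RNA level: Pdpn was at 4658 in ITGA8+ and 6176 in ITGA8-, and Itga8 was at 2215 in PDPN- and 737 in PDPN+.

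**Figure D1:**
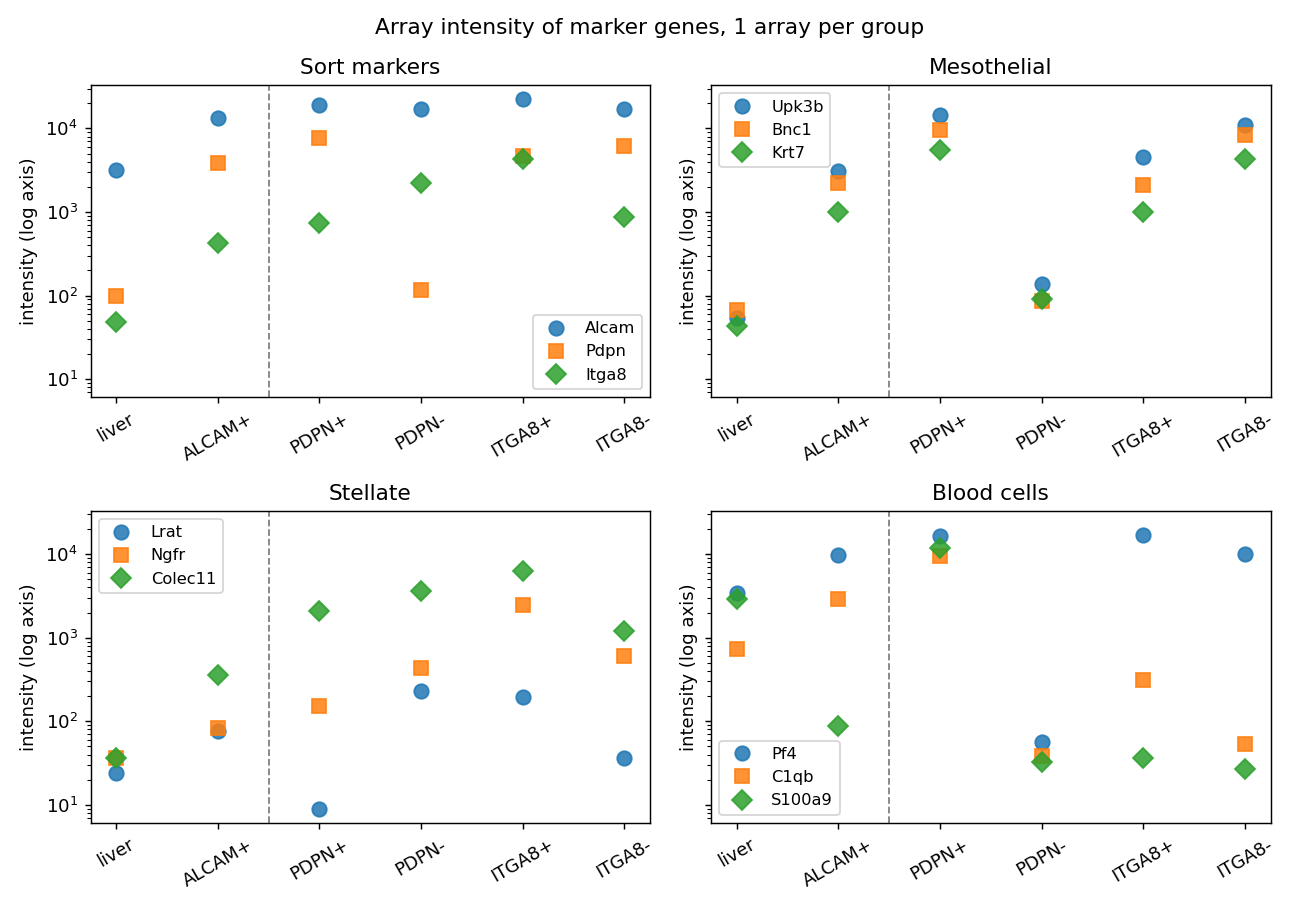
Intensity (log axis) of 3 genes per panel in each of the 6 groups, 1 point per gene and array. The dashed line parts the liver and ALCAM+ arrays from the 4 fraction arrays, which are on another scale. Upk3b was at 14424 in PDPN+ and 139 in PDPN-, and Lrat at 193 in ITGA8+ and 36 in ITGA8-.

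ALCAM+ cells were compared with liver cells to see what the first sort enriched. Relative to the median shift, mesothelial, collagen and mesenchymal transcription factor genes were higher in ALCAM+ cells, and erythroid genes were lower, as were 9 of 10 genes above the floor of a neutrophil list added after seeing the data. On the same footing Upk3b, a uroplakin of mesothelium, was 23.6-fold higher, Bnc1, a mesothelial and epithelial transcription factor, 14.5-fold, and Aldh1a2, which makes retinoic acid, 13-fold. Npnt, whose product nephronectin is a ligand of integrin alpha 8 beta 1, was 20.9-fold higher, Col6a2 19.3-fold, Col6a1 18.4-fold, Pdpn 18.0-fold and the small leucine-rich proteoglycan gene Fmod 16.3-fold. The genes lowest in ALCAM+ cells were Stfa2l1, 61.6-fold lower, Stfa3, 56.5-fold, and the neutrophil genes S100a9, 52.0-fold, and Camp, 25-fold. Epb42, of the red cell membrane skeleton, was 27.4-fold lower, Fn3k 25.1-fold, Ccdc92b 19.3-fold and the interferon-induced GTPase gene Irgm2 18.0-fold.

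By list, relative to the shift, 14 of 16 mesothelial members above the floor were 2-fold higher in ALCAM+ cells (median 2.94 log2), with Krt7 at 3.22 and Wt1 at 3.19; Cdh1 (0.03) and Krt18 (0.08) were not. Of 18 collagen and matrix genes 17 were higher (median 2.52), among them Col5a2 at 3.57 and Mgp at 3.43. Of 15 septum transversum and coelomic transcription factors 12 were higher (median 2.15), with Isl1 at 2.76 and Nr2f1 at 2.72. Among secreted growth factors 15 of 22 were higher, including Tgfb3 at 3.31 and Rspo1 at 2.88, and among portal fibroblast genes 8 of 12, including Mfap4 at 2.57 and Eln at 2.23. Of 14 stellate genes 10 were higher, led by Hand2 at 2.53 and Colec10 at 2.30, while Gfap was at -2.60. Of these 10, Pdgfrb and Hlx, the latter at 1.01, were just past 2-fold, and Hand2, Hlx and Foxf1 are also among the transcription factors counted above. Lrat, at 77 in ALCAM+, Ngfr, at 84, and Hgf, at 73, lay below the floor in both arrays and were not counted. Basement membrane (11 of 17 higher; Col4a6 at 3.12), smooth muscle (6 of 11; Synpo2 at 1.78), integrin (3 of 10; Itga3 at 2.74), retinoid handling (4 of 10; Crabp1 at 1.82) and cardiac muscle lists (3 of 7; Myl7 at 2.59) also stood apart upward.

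Genes of other cell types moved apart from each other. Of 19 erythroid genes 18 were lower in ALCAM+ cells (median -2.56), with Alas2, the first enzyme of haem synthesis in red cells, at -4.01 and Hbb-bh1 at -4.00. The megakaryocyte list went the other way, with 9 of 12 genes higher, among them the platelet receptor genes Gp1bb at 2.27 and Gp1ba at 2.12. Hepatoblast genes followed the shift, with 19 of 20 within 2-fold (median -0.16; Alb at -0.61, Cps1 at 1.88), as did 12 of 14 endothelial genes and 15 of 18 macrophage genes. Alb, at 15683 and 12832, and other abundant hepatoblast genes lie in the upper part of the intensity range, where differences can be compressed; of the 12 members below 5000 in both arrays, a choice made after seeing the data, 11 were within 2-fold (median -0.11). Of 20 proliferation genes 8 were lower relative to the shift, with Aurka at -1.79 and Mki67 at -1.57; as deposited the list median was 0.03, and relative to the shift -0.86. The housekeeping median was 0.26 as deposited and -0.63 relative to the shift. Skeletal muscle genes had 3 of 6 higher and stress genes 3 higher and 3 lower of 18. Xist was at -1.09 and the Y-linked Ddx3y at 1.51. As deposited, without the shift, more members were higher: 6 of 20 hepatoblast, 4 of 14 endothelial, 5 of 18 macrophage and 12 of 12 megakaryocyte genes, 13 of 14 stellate, 10 of 11 smooth muscle, 8 of 10 retinoid and 7 of 10 integrin genes, and 5 of 7 cardiac, 5 of 6 skeletal muscle and 10 of 18 stress genes. Lower as deposited were 12 of 19 erythroid and 0 of 20 proliferation genes, and 14 of 16 mesothelial genes were higher either way.

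As deposited, 4961 genes were 2-fold higher and 290 lower of 10989 above the floor, so 94.5% of the genes past 2-fold were higher. Relative to the shift the counts were 1694 and 1238, or 57.8% higher, against 53.7% with loess and 63.4% with quantile normalisation. Control probe sets for RNA quality differed between these 2 arrays. The fold of ALCAM+ over liver was 1.24 at the 3' and 0.801 at the 5' end of beta-actin, 0.506 and 0.173 at those of the transferrin receptor, and 1.49 and 1.35 at those of Gapdh, and 18S ribosomal RNA was at 0.287 to 0.599. Where a gene had another probe set above the floor, that probe set was also 2-fold as deposited for 54.2% of the higher and 69.4% of the lower genes.

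PDPN+ and PDPN- cells were compared to see how podoplanin splits ALCAM+ cells. Mesothelial, macrophage and megakaryocyte genes were higher in PDPN+ cells, and fewer genes were higher in PDPN- cells. The genes with the largest differences on the scale used included blood cell genes: the platelet chemokine genes Ppbp, 339-fold, and Pf4, 230-fold, the neutrophil genes S100a8, 263-fold, and S100a9, 243-fold, the eosinophil granule gene Prg2, 182-fold, Sla, 177-fold, the complement gene C1qb, 172-fold, and Stfa2l1, 144-fold. In PDPN- cells these 8 genes were at 1 to 56, below the floor of 109.0, so the sizes and order of these folds depend on the pseudocount. S100a9 was low in the other sorted arrays too, at 36 in ITGA8+, 27 in ITGA8- and, on the other scale, 89 in ALCAM+, while Pf4 was at 17111, 9917 and 9712. Higher in PDPN- cells were Tmem130, 22.3-fold, Anxa13, 18.1-fold, Lrat, which esterifies retinol for storage in stellate cells, 9.88-fold, Klrb1a, 9.59-fold, Nr1h4, the bile acid receptor gene, 9.18-fold, Dcx, 8.92-fold, the coagulation factor gene F9, 8.23-fold, and Foxq1, 7.97-fold. Several of these were low even in PDPN- cells, with Lrat at 231 and Klrb1a at 147.

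Of 19 mesothelial genes 16 were 2-fold higher in PDPN+ cells (median 4.93), with Bnc1 at 6.55, Upk3b at 6.54 and Upk1b at 6.46; Krt8, Cdh1 and Krt18 were between -0.75 and -0.62. Macrophage genes were higher in 17 of 17 (median 5.08; C1qc at 7.11, Lyz1 at 6.70), megakaryocyte genes in 12 of 12 (median 5.05; Vwf at 5.87, Clec1b at 5.67) and haematopoietic progenitor genes in 12 of 14. Clec1b encodes CLEC-2, the platelet receptor for podoplanin. Endothelial genes were higher in 7 of 10 (Flt4 at 4.28, Kdr at 3.28), and Gpr182 was at -1.41.

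Septum transversum and coelomic transcription factors were higher in 9 of 14 (Isl1 at 4.33, Wt1 at 3.42, Tbx18 at 3.04), collagen and matrix genes in 13 of 18 (Ogn at 2.71, Lox at 2.67), and basement membrane genes in 8 of 18 (Col4a6 at 4.22, Npnt at 3.50). Secreted growth factor genes were higher in 14 of 26, including Rspo1 at 5.49, Tgfb3 at 4.12 and Fgf9 at 3.96, and lower in 3: Bmp5 at -2.89, Cxcl12 at -1.36 and Gdf10 at -1.24. Retinoid handling genes were higher in 6 of 12, with Aldh1a2 at 5.18 and Aldh1a1 at 4.06. Portal fibroblast (6 higher and 2 lower of 12), cardiac muscle (6 of 6, Myl7 at 5.76) and stress genes (8 higher and 1 lower of 19, Ier3 at 3.95) also stood apart upward. The hepatoblast list stood apart downward with a median of -0.43 (percentile 0.03), and 4 of 23 genes lower, led by Foxa2 at -1.69 and Foxa1 at -1.39. Stellate genes were mixed, with 3 higher and 2 lower of 17 (median -0.29, percentile 3.92): Foxf1 at 1.67 and Ecm1 at 1.66 against Lrat at -3.30 and Ngfr at -1.41. Epithelial junction, erythroid, neural, gut and lung epithelium, integrin, smooth muscle, proliferation, housekeeping and sex-linked lists stayed in the central range of the random lists.

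In all, 2659 genes were higher in PDPN+ and 1052 in PDPN- cells of 13419, so 71.7% were higher, against 57.6% with loess and 58.1% with quantile normalisation. Another probe set was also 2-fold for 75.9% of the higher and 59.5% of the lower genes. In an alternative chosen after seeing the data, leaving out the genes of the blood lists gave 2601 and 1049 of 13345 genes, or 71.3% higher. So few genes were left out that the share could hardly move. Leaving out also every gene whose ALCAM+ minus liver difference was below the median, likewise chosen afterwards, gave 1581 and 363 of 6240, or 81.3% higher. This filter favours genes enriched in ALCAM+ cells, and the platelet gene Gp6, at 272 in ALCAM+ and 41 in liver, passes it. Neither count is free of blood genes.

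**Figure D2:**
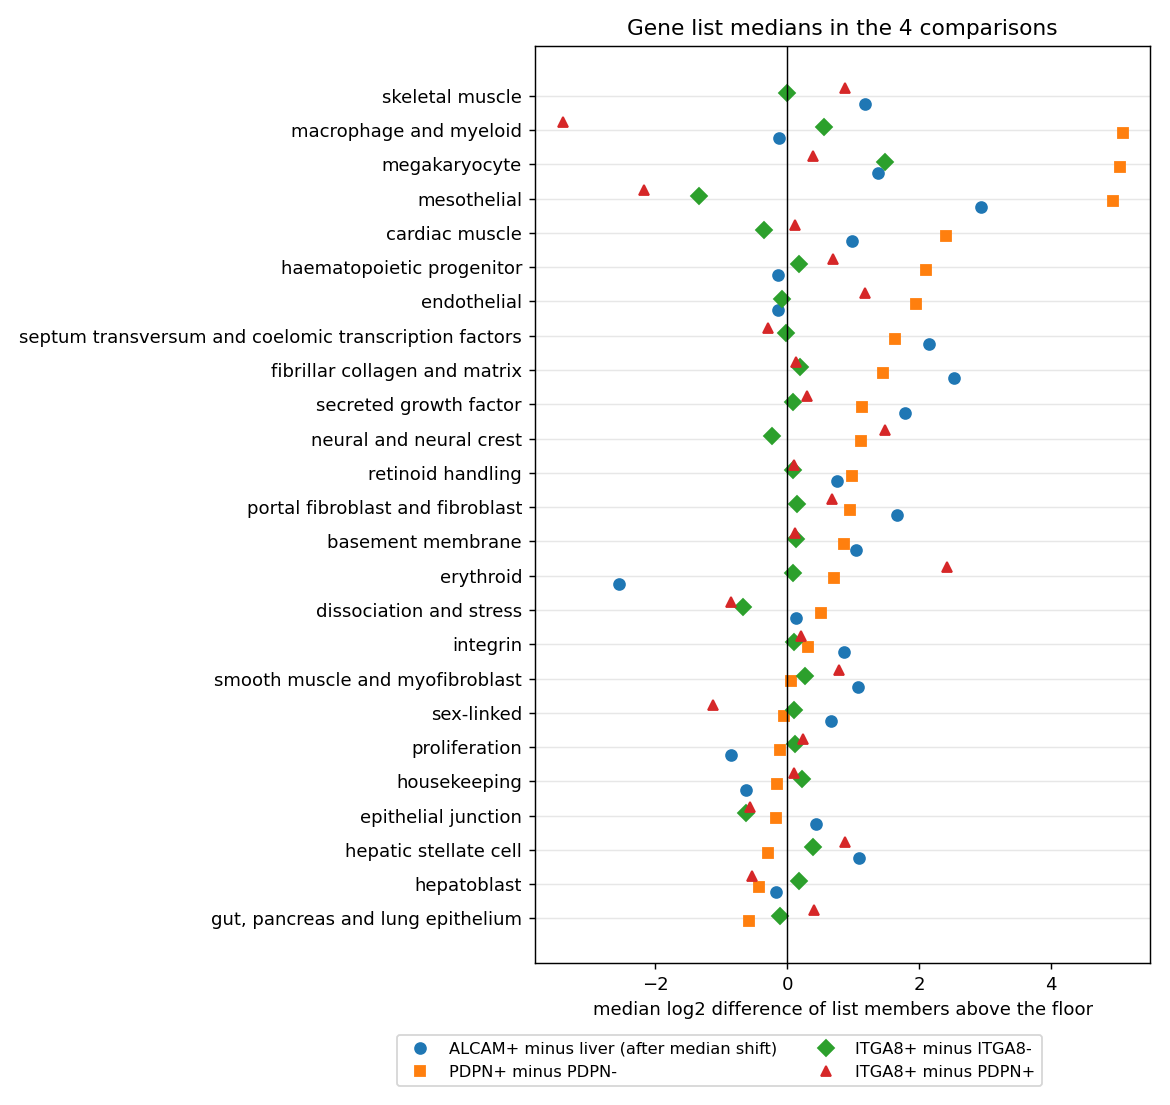
Median log2 difference of the members above the floor for each gene list, 1 symbol per comparison; ALCAM+ minus liver is drawn relative to its median shift. The mesothelial list lies at 4.93 in PDPN+ minus PDPN- and at -1.34 in ITGA8+ minus ITGA8-.

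ITGA8+ and ITGA8- cells were compared to see what goes with the integrin that the series names as a stellate marker. Megakaryocyte genes were higher in ITGA8+ cells in 9 of 12 and stellate genes in 6 of 18, and mesothelial genes were lower in 12 of 19. The megakaryocyte and mesothelial medians were smaller than in the PDPN split. The 8 genes highest in ITGA8+ cells were Sod3, extracellular superoxide dismutase, 8.94-fold, Actn2 8.80-fold, Spink4 8.68-fold, the platelet collagen receptor gene Gp6 7.91-fold, the diacylglycerol kinase gene Dgkk 7.15-fold, Gp1bb 6.25-fold, the dipeptidase gene Dpep1 6.24-fold and Igfbp7 6.22-fold. Sod3, at 136, and Spink4, at 149, were low in ITGA8+ cells. Lower were the tight junction gene Cldn15, 12.2-fold, Pnoc, 8.85-fold, the extracellular matrix gene Frem2, 7.11-fold, Ooep, 7.0-fold, Lrrn4, 6.77-fold, Krt15, 6.59-fold, Bcar3, 6.53-fold, and Tm4sf5, 6.34-fold.

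Of 18 stellate genes 6 were 2-fold higher in ITGA8+ cells and none lower (median 0.40, percentile 99.08). They were Colec11 at 2.37, Lrat at 2.01, Ngfr at 2.01, Colec10 at 1.23, Reln at 1.14 and Lhx2, a transcription factor of stellate cells, at 1.12; Hgf was at -0.77. Of 19 mesothelial genes 12 were lower (median -1.34), with Cldn15 at -3.61, Lrrn4 at -2.76 and Krt19 at -2.64, and Slpi at 1.53. Epithelial junction genes were lower in 5 of 17 (median -0.63; Cdh3 at -1.77, Cldn6 at -1.51), and stress genes in 4 of 19 (median -0.67; Klf6 at -1.20, Zfp36 at -1.14). Megakaryocyte genes were higher in 9 of 12 (median 1.48; Vwf at 2.18, Gp5 at 1.98), and macrophage genes in 4 of 12 (median 0.56; C1qb at 2.24, Fcer1g at 1.67).

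Basement membrane genes went both ways: Lama1 at 1.32, Col4a2 at 1.18, Col4a1 at 1.17 and Lama2 at 1.11 were higher, while Col4a6 at -2.10, Lama5 at -2.06 and Col4a5 at -1.80 were lower. Secreted growth factor genes split likewise, with Gdf10 at 1.98 and Bmp5 at 1.75 against Fgf9 at -1.99, Rspo1 at -1.65 and Wnt2b at -1.57. In the portal fibroblast list Meox2 was at 1.95 and Thy1 at 1.84, and Dpp4 at -1.89. The medians of these lists, and of the collagen, integrin, smooth muscle, retinoid, transcription factor, hepatoblast, erythroid, progenitor, endothelial, cardiac, skeletal muscle, neural, gut, proliferation, housekeeping and sex-linked lists, stayed in that range.

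In all, 736 genes were higher in ITGA8+ and 825 in ITGA8- cells of 13866. Higher genes made up 47.1% of these, against 50.6% with loess and 60.3% with quantile normalisation. Another probe set was also 2-fold for 20.4% of the higher and 29.0% of the lower genes, and went the same way for 75.7% and 81.8%.

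Across 12793 genes above the floor in both splits, the PDPN and ITGA8 differences had a Pearson r of -0.160 and a Spearman rho of -0.121; genes are not independent replicates, and the 2 differences share no array. Genes higher in both PDPN+ and ITGA8- numbered 315, where independent lists would share 141.9, and genes higher in both PDPN- and ITGA8+ 96, against 40.8. Genes higher in PDPN+ and ITGA8+ numbered 139 against 107.4, and in PDPN- and ITGA8- 31 against 53.9. The ALCAM+ array, which should lie between its fractions if arrays were on 1 scale, lay within 0.5 log2 of that range for 24.3% of genes in the PDPN split and 9.81% in the ITGA8 split. After shifting it by its median the shares were 68.4% and 80.1%, against 55.9% and 52.5% for the liver array.

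**Figure D3:**
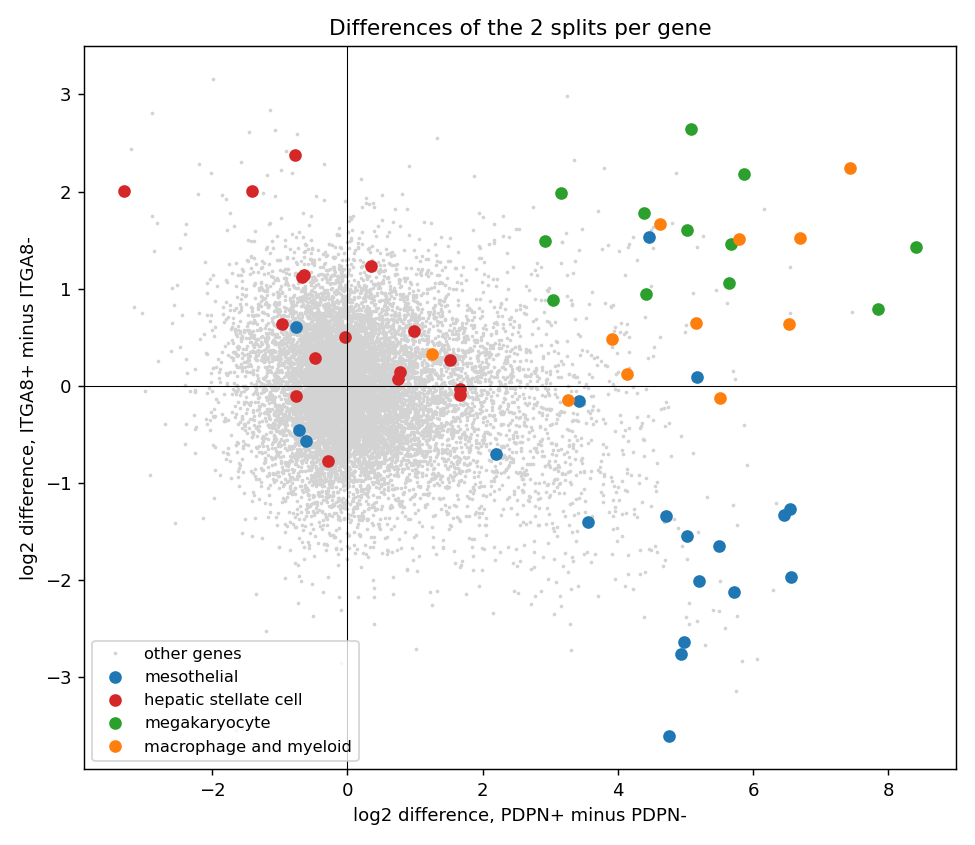
Log2 difference of each gene above the floor in both splits, PDPN+ minus PDPN- on the horizontal and ITGA8+ minus ITGA8- on the vertical axis, with 4 gene lists in colour. Mesothelial genes lie to the right and mostly below 0, with medians of 4.93 and -1.34, and megakaryocyte genes to the right and above 0, with medians of 5.05 and 1.48.

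ITGA8+ and PDPN+ cells, the 2 positive fractions, were compared with each other; this comparison crosses the 2 sorts and shares an array with each split. Erythroid genes were higher in ITGA8+ cells in 19 of 19 and stellate genes in 8 of 18. Macrophage genes were higher in PDPN+ cells in 15 of 18, mesothelial genes in 14 of 19, and genes of the neutrophil list in 13 of 14. The largest differences toward ITGA8+ were of Ctse, cathepsin E, 78.4-fold, Mela, which matches multi-copy sequences, 72.0-fold, Fap, fibroblast activation protein, 50.2-fold, Bcat1 32.3-fold, Dcx 26.1-fold, Gabrb2 25.4-fold, the potassium channel gene Kcnn4 25.4-fold and Arhgdig 23.7-fold. Toward PDPN+ they were of S100a8, 255-fold, S100a9, 229-fold, Stfa2l1, 119-fold, the macrophage genes Cd5l, 117-fold, and C1qc, 112-fold, Camp, 61.1-fold, Prg2, 50.7-fold, and Stfa3, 50.1-fold; these 8 were at 4 to 45 in ITGA8+ cells.

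Of 19 erythroid genes 19 were higher in ITGA8+ cells (median 2.43), with Epor at 4.38 and Klf1 at 4.37, although the same list had a median of 0.09 between ITGA8+ and ITGA8-. Stellate genes were higher in 8 of 18 (median 0.88; Ngfr at 3.87, Lrat at 3.06, Lhx2 at 2.26). Endothelial (11 of 19, Mmrn2 at 3.04), neural (5 of 8, Dcx at 4.71) and smooth muscle lists (3 of 12, Myh11 at 2.02) also stood apart upward. So did the portal fibroblast (4 higher and 2 lower of 13, Thy1 at 3.61) and progenitor lists (6 higher and 4 lower of 14, Myb at 3.34). The progenitor median turned to -0.14 with specific probe sets and the smooth muscle median to -0.018 with the higher floor. Mesothelial genes were lower in 14 of 19 (median -2.17; Cldn15 at -4.20), macrophage genes in 15 of 18 (median -3.40), hepatoblast genes in 9 of 23 (median -0.53), stress genes in 8 of 19 (Hmox1 at -3.25), epithelial junction genes in 7 of 17 (Cldn1 at -2.55) and sex-linked genes in 3 of 5 (Kdm5d at -1.49, Ddx3y at -1.32). In all, 2269 genes were higher in ITGA8+ and 1992 in PDPN+ cells of 14087, and another probe set was also 2-fold for 40.5% and 48.4%.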

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

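In this part the tests on spike-ins, the highest signal bin, the share of blood genes higher in PDPN+, neutrophil transcripts in ALCAM+ and the erythroid list were chosen after their results were seen, and those on the trend over signal bins and on macrophage and megakaryocyte transcripts in ALCAM+ before. Among data outside the gene comparisons, 91 probe sets that name no gene were 2-fold higher in ALCAM+ than in liver after the median shift. On the same footing 403 were lower, of 1159 above the floor. In the PDPN split 952 such probe sets were higher in PDPN+ and 91 lower of 2270, against 2659 and 1052 of 13419 genes. In the ITGA8 split 62 were higher and 220 lower of 2540, and in ITGA8+ minus PDPN+ 473 and 552 of 2621. The cause of these imbalances was not tested. The 18 spike-in probe sets, which measure bacterial and phage transcripts added to each sample, had a median fold of 1.014 for ALCAM+ over liver, with a range of 0.836 to 2.603.

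Most genes had more signal in ALCAM+ than in liver, by a median of 0.90 log2. The spike-in probe sets had a median of 1.014, but disagreed on whether the ALCAM+ array was brighter as a whole. Those of the bioB transcript were at 0.901 to 1.22, which argues against it, and those of bioC at 2.30 to 2.60, which go with it. Those of bioD and cre were at 0.836 to 1.014, at intensities of 4885 to 26853, where differences can be compressed. A brighter array therefore stays open. The median difference fell over 10 bins of mean signal (Spearman rho -0.879; -0.833 without the lowest bin, which the floor itself raises), in line with an array response that depends on signal level. The highest bin lay -0.302 from the overall median (-0.345 to -0.254 over 2000 resamples of genes), which spans the 0.3 set as a limit. The resamples treat genes as independent and measure no spread between arrays. A need for the whole interval to pass was added after the value was seen. By it, 1 factor for all genes, such as a few abundant transcripts filling the liver array, stays open. RNA quality stays open too, since the ALCAM+ over liver fold was 1.24 at the 3' and 0.801 at the 5' end of beta-actin, as does a real difference in RNA content, which was not tested.

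White blood cell and platelet transcripts were far higher in PDPN+ than in PDPN-: Pf4 was at 16547 and 56, S100a9 at 11903 and 33, and C1qb at 9462 and 39, and of 42 neutrophil, macrophage and megakaryocyte genes above the floor (Elane and Prtn3 are in 2 of the lists) 97.6% were 2-fold higher, which restates the pattern and leaves open whether cells of these types were in the PDPN+ sample, since the ALCAM and PDPN gates would remove cells that carry neither protein. The neutrophil list had a median intensity of 209 in PDPN+ against 32 in ITGA8+ and 25 in ITGA8-, and C1qb was at 315 in ITGA8+ and 54 in ITGA8-. In the other set of arrays the neutrophil median was 28 in ALCAM+ and 72 in liver, and C1qb was at 2898 in ALCAM+. That set is on a lower scale, with the liver array a median of -2.32 log2 from the PDPN fractions. Its levels therefore cannot be ranked against those of PDPN+. Whether neutrophil transcripts were already in the ALCAM+ population stays open. The test cannot decide, since the neutrophil list was added after these same arrays, with their low ALCAM+ and high PDPN+ levels, had been seen. It crosses the 2 sets of arrays, relative to the median of -1.61 over all genes, with ALCAM+ levels below the floor raised to it. The 6 members above 1000 in PDPN+ had a median ALCAM+ minus PDPN+ -2.59 from that of 15 mesothelial genes. The highest of the 6 was at -2.62 and the lowest mesothelial gene at -1.90. In the test first set, over all members above the floor, the gap was -1.77, within the 2 log2 allowed for presence. That test was set aside because most ALCAM+ levels lay below the floor. Over all members above the floor, with ALCAM+ levels not raised, the macrophage median relative to the mesothelial list was -0.047. It would be so if these transcripts were already in the ALCAM+ population. Over the 13 macrophage members above 1000 in PDPN+, with ALCAM+ levels raised, the median was -0.91, against -0.64 for the 15 mesothelial genes. Both values cross the 2 sets of arrays. Within the set of the fractions the macrophage list had a median intensity of 1916 in PDPN+, 188 in ITGA8+ and 123 in ITGA8-. The mesothelial list was at 2891, 756 and 1609. Whether macrophage transcripts were already in the ALCAM+ population therefore stays open. Megakaryocyte transcripts were present in ALCAM+, at a median intensity of 1958 against 261 in liver. Over all members above the floor, their median relative to the mesothelial list was 2.35, above the range set for the test. The upper limit of that range was dropped after the value was seen because it does not bear on presence. What the excess comes from was not tested.

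Erythroid transcripts were higher in ITGA8+ than in PDPN+. Their median between ITGA8+ and ITGA8- was 0.087, which argues against a difference that goes with ITGA8. The larger of the all-gene and housekeeping medians was 0.11, which argues against array scaling. In 19 genes the lower ITGA8 fraction exceeded the higher PDPN fraction by a median of 2.36, which largely restates the pattern and is no separate support. A difference between the 2 sorts remains a candidate explanation. What in the sorts differed is not given in the sources used here.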

How the results depend on the processing

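The alternatives with pseudocounts, another probe set, re-centred substitutes, genes of the blood lists left out, abundant hepatoblast genes left out or a shifted ALCAM+ array were chosen after seeing the data. The others were planned. With 1 array per group nothing passes a test, and signal over background limits low genes. Of 108 alternative gene counts 53 stayed within 1.5 times. For ALCAM+ minus liver (4961 higher, 290 lower) the others were 1694 and 1238 re-centred, 1421 and 1227 with loess, 2732 and 1579 with quantile normalisation, 3204 higher with the mean of probe sets, 509 lower with no floor, 2251 and 94 with a floor at the 75th percentile, 160 lower with a pseudocount of 100, 1456 and 69 at 4-fold, and 1073 and 34 with another probe set. With the mean of the 4 fractions for ALCAM+ they were 11831 and 155 (2084 and 2076 re-centred), with the PDPN fractions 11365 higher, and with the ITGA8 fractions 12294 and 70; these cross the 2 sets of arrays, which differ in scale. For PDPN+ minus PDPN- (2659 and 1052) they were 1698 higher with quantile normalisation, 1671 lower with no floor, 1285 and 652 with the higher floor, 1210 and 108 at 4-fold, 641 and 160 with another probe set, 1581 and 363 without blood list genes and genes below the median ALCAM+ minus liver difference, and 10470 and 135 with ALCAM+ for PDPN- (1080 higher re-centred). For ITGA8+ minus ITGA8- (736 and 825) they were 452 higher with the mean of probe sets, 1294 higher with no floor, 455 and 502 with the higher floor, 544 lower with quantile normalisation, 459 and 538 with a pseudocount of 100, 47 and 64 at 4-fold, 58 and 78 with another probe set, and 10921 and 51 with ALCAM+ for ITGA8-. For ITGA8+ minus PDPN+ (2269 and 1992) they were 3973 higher with no floor, 1250 and 1265 with the higher floor, 568 and 484 at 4-fold, and 328 and 301 with another probe set. A higher floor, a higher threshold and the need for another probe set count fewer genes by construction; for the rest the cause was not tested. The correlation of the splits was -0.172 with the mean of probe sets, -0.153 with specific probe sets, -0.125 with no floor, -0.174 with the higher floor, -0.179 with loess, -0.192 with quantile normalisation, and -0.157 and -0.159 with pseudocounts of 1 and 100. The share of genes with ALCAM+ within its fractions was 13.9%, 41.1% and 68.4% (PDPN) and 3.03%, 28.3% and 80.1% (ITGA8) at tolerances of 0 and 1 and after the shift. Of 952 alternative list medians 802 stayed within 0.5 log2. In all 64 changed sign, 10 of them of lists that stood apart from random lists as deposited and the rest of lists that did not, such as hepatoblast (-0.16), endothelial (-0.15), macrophage (-0.12) and progenitor genes (-0.14) in ALCAM+ minus liver re-centred. The 10 were these. In ALCAM+ minus liver the proliferation median was -0.11 with the mean of probe sets, -0.14 with specific probe sets, -0.86 re-centred, -0.64 with loess and -0.51 with quantile normalisation, and the housekeeping median -0.63, -0.15 and -0.012 with the last 3. In ITGA8+ minus PDPN+ the smooth muscle median was -0.018 with the higher floor and the progenitor median -0.14 with specific probe sets. Of 4753 alternative gene values 103 changed sign, 19 of them in ALCAM+ minus liver re-centred (Alb at -0.61). Of genes past 2-fold as deposited 11 values did: in ALCAM+ minus liver Sox9 (-0.15) and Tbx5 (-0.29) with loess, and Mcm2 (-0.15) and Acta2 (-0.34) with specific probe sets; with specific probe sets also Tnnt2 (-0.093) in the PDPN split, Tbp (0.49) in the ITGA8 split, and Meis1 (-0.14), Ptprc (0.26), Tbp (0.014) and Itga5 (-1.23; -0.17 with the mean of probe sets) in ITGA8+ minus PDPN+.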

Other observations

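A hypothesis noted from the lists is that 1 axis from mesothelial to stellate genes lies behind both splits. The test, set before its result was seen, took the 1000 genes with the largest absolute PDPN difference, leaving out blood list genes, and gave a Pearson r of -0.295 with the ITGA8 difference. That meets 1 condition set for the test, an r of -0.2 or below, but choosing genes by the size of 1 difference makes r more negative by itself: from -0.181 over all such genes the choice alone would give -0.243. The other condition, a move toward 0 by at least 0.03 without the mesothelial and stellate list members and every gene correlated with them, was run for the list members alone, since with 1 array per group no correlation between genes was computed: r was -0.268 over 983 genes, a move of 0.027. The test therefore leaves the hypothesis open. Of the 1000 genes 948 were higher in PDPN+, with a median ITGA8 difference of -0.33, and 52 were higher in PDPN-, with a median of 0.38. Only members of the blood lists were left out, so blood genes in no list, such as Gp6, could stay among the 1000.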
